A study of Homo sapiens with 80 samples.

How the data were processed

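RNA was isolated with the RNeasy Mini kit from core-needle biopsies kept in RNAlater, per the labels' protocols, and biotin-labelled cRNA was hybridised to Affymetrix arrays. The series held 80 arrays, 1 biopsy per patient, all from people with metastatic colorectal cancer before treatment with cetuximab alone. Per the submitters' processing notes, the values were made with GCOS 1.1.1.052, the scanner maker's software. The background step, the scaling target and the summary of probes were not given in the sources used here.

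The deposited table held a linear intensity for each of 22277 probe sets on each array. Values ran from 0.2 to 453787.7 and none was 0 or negative. The mean of each array after trimming 2% at either end lay between 1500.4 and 1500.7, a spread of 0.0182%, which is under the limit of 5% set before the data were examined for treating the arrays as already scaled by the authors. No further scaling was therefore applied, and values were analysed as log2(intensity + 16). Differences are on that scale, which understates the change of dim genes. No pair of arrays held identical values.

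Probe sets were named through the annotation of the platform. Of all probe sets, 62 were controls, 19033 had 1 gene symbol and were kept, 31 with 1 symbol were left out, 1043 had several symbols, and 2108 were not listed in the annotation used. Gene numbers were matched to RefSeq genes (assembly GRCh38.p14), which changed 0 symbols and gave the chromosome names. The array values carried no genome build, so no coordinates are given. Each of the 11939 genes was represented by its probe set with the highest mean, and 8976 genes lay above their array's median on at least 3 arrays and were tested. Other probe sets of a gene can differ from the chosen one, so the mean of all probe sets of a gene was an alternative.

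Biopsies were grouped by the organ in the labels into 61 from liver, 6 from abdomen, 3 from lung and 3 from large bowel. The remaining 7, from sites with too few biopsies for a group or, for 1 biopsy, with an uncertain site, entered only the comparison of liver with all other sites. The other site comparisons were contrasts in a 4-group fit, so that groups shared an estimate of spread. Because each patient gave 1 biopsy, p-values rest on the spread between patients. The shared estimate comes mostly from the 61 liver biopsies. Where a small group varied more than liver, its SE and p-value can be too small, and where it varied less, too large. For example, MMP13 had an SD of 4.28 in abdomen against 0.44 in liver, and ORM1 0.22 in large bowel against 3.32. Fits that leave out a biopsy have the same limit. The number of arrays limits the precision, above all for the groups of 3.

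Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. EREG levels in liver were tested as a number, standardised over all 80 arrays, with the mean of the hepatocyte list as a covariate. The EREG fit outside the liver had no such covariate. A second EGFR ligand planned alongside EREG was not analysed here. In addition, 29 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. They covered hepatocytes, urea cycle and amino acid catabolism, drug and bile acid metabolism, acute phase and complement, cholangiocytes, liver macrophages and sinusoid, and alveoli and airway. Others covered smooth muscle, skeletal muscle, adipocytes, mesothelium, fibroblasts and matrix, endothelium, T and NK cells, B and plasma cells, neutrophils and monocytes, macrophages, the interferon gamma response and red blood cells. The rest covered intestinal epithelium, mature colonocytes, goblet cells, Wnt targets and stem cells, EGFR ligands and receptors, MAPK output, proliferation, hypoxia and glycolysis, immediate early stress and ribosomal proteins. Fry asks whether a list moves on balance in 1 direction and does not compare it with other genes. A list mean is the mean over its genes of log2 values standardised over the 80 arrays, and in correlations with the hepatocyte mean the genes shared with the hepatocyte list were left out. EREG itself was not counted in the EREG fit. Several lists share genes, among them the hepatocyte list with the lists of liver metabolism, the macrophage list with that of liver macrophages, and the cholangiocyte list with that of intestinal epithelium. The mesothelium list shares HP and C3 with the acute phase list.

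Correlations across biopsies are given as Pearson's r and Spearman's rho with 100000 permutations, two-sided, for which the smallest p is 1e-05, and again without the 2 biopsies farthest from the median of EREG, or of the hepatocyte mean in the second family below. The families were 7 partners of EREG and 28 list means set against the hepatocyte mean. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table (1.17.8), were also used.

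Named genes followed a rule fixed beforehand. In each comparison of sites it takes the 15 largest rises and the 15 largest falls past the threshold, up to 4 members of each list with the smallest adjusted p, and always EREG, TGFA, EGFR and DUSP6. The EREG fit used the same rule without the last clause. The genes in the text are a part of those the rule takes, chosen to represent the lists.

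Alternatives were other pseudocounts, quantile normalization, other filters on dim genes, other choices of probe set, eBayes without trend or robust, and array weights. Further ones were covariates for RNA quality (the ratio of 3 prime to 5 prime control probe sets of GAPDH and ACTB) and for the hepatocyte mean, and a fit with the middle number of the sample titles as a factor. That number took 10 values and its meaning was not given, so it was treated as a possible batch. Each biopsy of the groups of 6 or 3 was also left out in turn. Some alternatives were added after the data had been seen: the largest pseudocount, the intestinal epithelium mean as a further covariate, the 7 biopsies of other sites left out, correlations within title numbers, and list correlations outside the liver. So were analyses without 5 arrays whose mean correlation with the other arrays lay more than 3 scaled median absolute deviations below the median, that is under 0.825.

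The 6 site comparisons and the EREG fit in liver were tested on simulated data, but not the EREG fit outside the liver, the permutation correlations, the chromosome test or Dixon's test. In these data 200 genes, 50 at each size, were shifted. Among 8976 genes, shifts of 1 on the log2 scale were recovered in 82% of cases for liver against all other sites, 58% for abdomen against liver, 26% for lung against liver, 44% for large bowel against liver, 34% for lung against abdomen and 34% for large bowel against abdomen. Shifts of 2 were recovered in 100%, 94%, 76%, 86%, 70% and 66%. In the EREG fit, run on 8975 genes, slopes of 0.5 were recovered in 82% of cases. Between 1 and 15 of the 8756 unchanged genes, or 8755 in the EREG fit, were called, as were 0 of 27 unchanged lists in every comparison. The simulated values were residuals shuffled between all arrays. All simulated groups therefore had the same spread, and EREG was not linked to the share of liver cells or tumour in a biopsy. Recovery and false calls need not be the same in the real data, where some spreads differ between groups and EREG varies with the hepatocyte mean. The simulated lists were genes drawn at random, unlike the cell type lists, whose genes can move together. They therefore do not show how often camera's preset correlation gives false calls for such lists.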

Results

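Core-needle biopsies of metastatic colorectal cancer were taken before treatment with cetuximab, an antibody that blocks the EGF receptor (EGFR), and their RNA was profiled on expression arrays. Of 80 biopsies, 61 came from the liver, 6 from the abdomen, 3 from the lung, 3 from the large bowel and 7 from other sites. The study was set up to look for expression that varies with the response to cetuximab. Treatment outcome was not analysed here, so the comparisons concern the biopsy site and, in liver, the level of EREG (epiregulin, a ligand of EGFR). Array medians ran from 339.7 to 587.8 intensity units, and the ratio of 3 prime to 5 prime control probe sets ran from 0.965 to 1.56 for GAPDH and from 1.12 to 3.35 for ACTB.

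Liver biopsies carried high levels of the transcripts of liver cells. Albumin (ALB) was higher in liver than at all other sites by 5.89 ± 0.81 on the log2 scale (SE, 61 against 19 biopsies, adjusted p = 3.08e-07), and all 61 liver biopsies lay above the median of the other 19. Fibrinogen chains rose alike, FGA by 6.04 ± 0.83 (adjusted p = 3.08e-07) and FGG by 6.17 ± 0.79 (adjusted p = 6.87e-08), as did the acute-phase protein CRP by 6.16 ± 0.78 (adjusted p = 4.97e-08). In the other direction, the collagenase MMP13 was lower in all 61 liver biopsies than the median of the others, by -2.78 ± 0.39 (adjusted p = 6.02e-07), and the microfibril gene MFAP5 by -2.84 ± 0.45 (adjusted p = 5.22e-06). Of 8976 genes, 1053 passed the threshold, 496 higher and 557 lower in liver, and 439 of them differed by at least 1.

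All 31 measured hepatocyte genes and all 17 acute phase and complement genes rose in liver, also when adjusted over the list alone (camera adjusted p = 3.45e-54 and 4.22e-30). Of 14 genes of the urea cycle and amino acid catabolism 12 rose, and 14 adjusted over the list alone. Of 17 genes of drug and bile acid metabolism 14 rose, and 16 adjusted over the list alone. These 4 lists also passed with an estimated correlation (adjusted p = 0.0249, 0.0249, 0.0445 and 0.0445). Examples are the transport proteins APOA2 at 5.65 ± 0.91 and TF at 5.38 ± 0.93, CYP2E1 at 4.81 ± 0.87 and CYP2C8 at 4.59 ± 0.90, both cytochromes P450, UGT2B4 at 4.86 ± 0.84, and the bile acid conjugating enzyme BAAT at 3.53 ± 0.68. HPD rose by 5.19 ± 0.92, MAT1A by 4.87 ± 0.76, the urea cycle enzyme ARG1 by 4.05 ± 0.82 and ALDH4A1 by 2.29 ± 0.40. The acute-phase proteins ORM1 and HP rose by 5.93 ± 0.88 and 4.54 ± 0.76. Among liver macrophage and sinusoid genes 5 of 11 rose, 7 adjusted over the list alone, with FCN3 at 2.80 ± 0.56, CRHBP at 2.83 ± 0.68 and CLEC1B at 2.46 ± 0.56 (camera adjusted p = 2.23e-06, but adjusted p = 0.38 with an estimated correlation). FABP1, made by enterocytes and hepatocytes alike, rose by 2.01 ± 0.54 and the bicarbonate transporter SLC4A4 by 1.46 ± 0.39. In a fit with the hepatocyte mean as a covariate 9 of the genes in this paragraph turned direction: BAAT, FCN3, SLC4A4, CYP2E1, CYP2C8, ARG1, HPD, CRHBP and CLEC1B.

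Some genes of fibroblasts, goblet cells and neutrophils were lower in liver. Their lists passed at camera's preset correlation but not at an estimated one, and by fry for goblet cells (adjusted p = 0.00746) and neutrophils (adjusted p = 0.0128) but not for fibroblasts (adjusted p = 0.107). Of 20 fibroblast and matrix genes 4 fell and 16 did not pass, with 7 falling when adjusted over the list alone (camera adjusted p = 0.00488, but adjusted p = 0.749 with an estimated correlation). They included the collagen COL11A1 at -2.58 ± 0.61, the protease CTSK at -1.69 ± 0.35 and the gelatinase MMP2 at -1.58 ± 0.37. Outside that list fell LRRC15 at -2.42 ± 0.36, FBLN1 at -2.36 ± 0.37 and SPON1 at -2.11 ± 0.39. So did the homeobox genes MEOX2, PRRX1 and HOXC6, at -2.05 ± 0.35, -2.03 ± 0.27 and -2.01 ± 0.43. Goblet cell genes fell in 3 of 8, also adjusted over the list alone: the mucin MUC2 at -2.05 ± 0.49, FCGBP at -1.72 ± 0.44 and SPINK4 at -1.35 ± 0.44 (camera adjusted p = 0.0185, but adjusted p = 0.471 with an estimated correlation). Among 14 neutrophil and monocyte genes 5 fell and 1 rose, and 7 and 1 adjusted over the list alone. S100A8 and S100A9 were at -1.23 ± 0.35 and -1.20 ± 0.29, and the cytokine IL1B at -0.86 ± 0.22 (camera adjusted p = 0.00841, but adjusted p = 0.534 with an estimated correlation).

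Immediate early genes fell in 4 of 13, 5 adjusted over the list alone, with FOS at -1.19 ± 0.28 and EGR3 at -0.82 ± 0.23 (camera adjusted p = 0.0097, but adjusted p = 0.471 with an estimated correlation). In the MAPK output list 2 of 22 genes fell, also adjusted over the list alone, PLAUR at -0.77 ± 0.26, which turned in that fit, and EMP1 at -0.93 ± 0.30 (camera adjusted p = 0.037, but adjusted p = 0.742 with an estimated correlation). The interferon gamma list fell in 2 of 15, also adjusted over the list alone (camera adjusted p = 0.0119, but adjusted p = 0.742 with an estimated correlation). The B-cell chemokine CXCL13 fell by 2.04 ± 0.48. Adipocyte genes parted, with 3 of 11 rising and 5 falling, among them the hormone ADIPOQ at -1.43 ± 0.32 (camera adjusted p = 0.763). EGFR itself rose by 0.50 ± 0.17 (adjusted p = 0.0429), with 50 of 61 liver biopsies above the median of the others. EREG at 0.51 ± 0.55 (adjusted p = 0.578), the EGFR ligand TGFA at 0.06 ± 0.22 (adjusted p = 0.883) and the ERK phosphatase DUSP6 at -0.13 ± 0.15 (adjusted p = 0.618) did not pass. Intestinal epithelium genes, the markers of the tumour cells, had a median of -0.12 and 1 of 20 passed (camera adjusted p = 0.736).

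With a stricter filter that asked genes to lie above the median on 50% of arrays, 695 genes passed, and without the 5 arrays that stand apart 791. The split turned to 579 higher and 411 lower with quantile normalization, 369 and 326 with the stricter filter and 450 and 439 with the hepatocyte covariate. Only 216 of the 1053 genes were among the 889 of that last fit. Without the 5 arrays EGFR and PLAUR did not pass. In none of the lists past the threshold, in any comparison, did the median, the mean and camera's direction differ in sign, whereas they differed in 35 of all 232 list results.

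**Figure D1:**
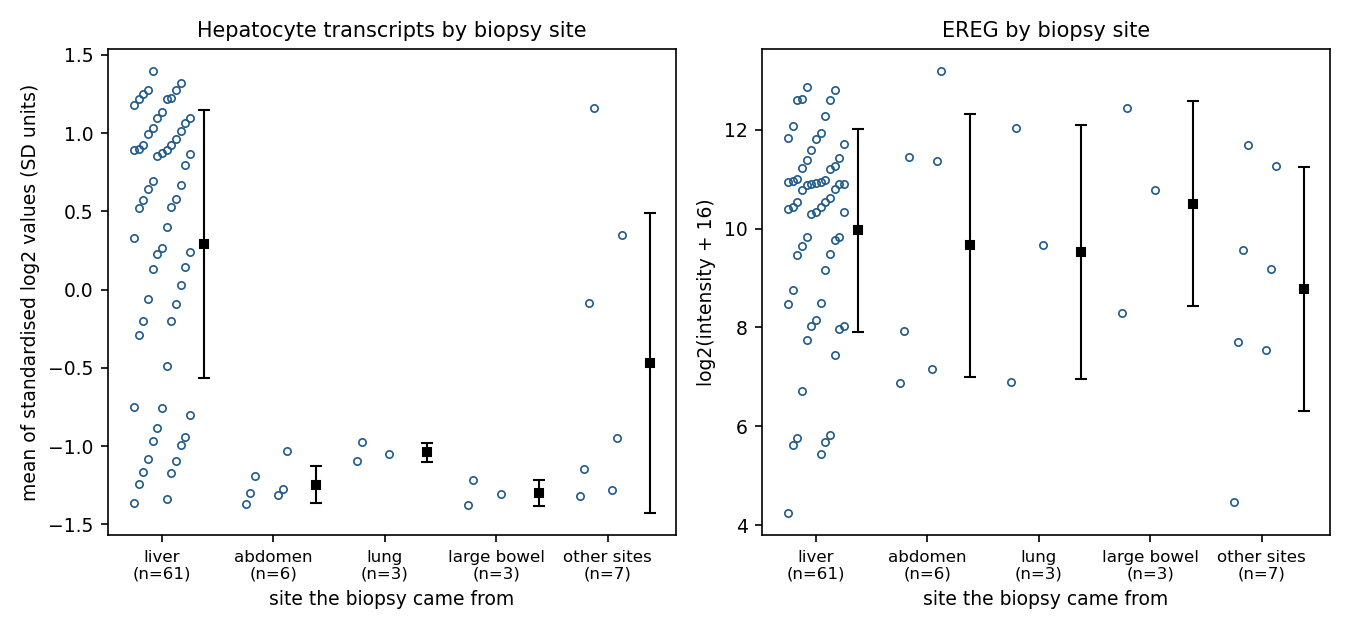
Mean of standardised log2 values of the hepatocyte list (left, in SD units) and log2(intensity + 16) of EREG (right) for each of 80 biopsies by site; squares and bars give the mean and SD. The hepatocyte mean ran from -1.36 to 1.39 in liver and stayed at or below -0.975 in abdomen, lung and large bowel, while EREG covered a wide range at every site.

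The hepatocyte mean varied widely within the liver group, at 0.29 ± 0.86 (SD, n = 61), against -1.25 ± 0.12 in abdomen (n = 6), -1.04 ± 0.06 in lung (n = 3) and -1.30 ± 0.08 in large bowel (n = 3). Of the 61 liver biopsies, 8 lay at or below the highest value of those 3 sites, and 4 of the 7 biopsies of other sites lay above it. Within liver, the means of 23 of 28 lists moved with the hepatocyte mean, 11 upward and 12 downward, and 25 by Spearman's rho.

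The lists of liver function rose most closely with it: acute phase and complement (r = 0.992, rho = 0.985), urea cycle and amino acid catabolism (r = 0.936, rho = 0.984). Next came drug and bile acid metabolism (r = 0.931, rho = 0.980) and liver macrophage and sinusoid (r = 0.834, rho = 0.893). Each had an adjusted permutation p of 2.8e-05, from a p of 1e-05, the smallest possible. Mesothelium (r = 0.707, rho = 0.623), adipocyte (r = 0.673, rho = 0.707), and macrophage means (r = 0.534, rho = 0.607) rose too. So did B and plasma cell (r = 0.505, rho = 0.539), T and NK cell (r = 0.426, rho = 0.443), endothelium (r = 0.387, rho = 0.423) and mature colonocyte means (r = 0.288, rho = 0.293). Falling with it were the means of hypoxia and glycolysis (r = -0.687, rho = -0.713), MAPK output (r = -0.665, rho = -0.715), and ribosomal proteins (r = -0.630, rho = -0.657). Next were Wnt targets and stem cells (r = -0.596, rho = -0.688), intestinal epithelium (r = -0.583, rho = -0.740), immediate early stress (r = -0.527, rho = -0.563) and proliferation (r = -0.519, rho = -0.624). EGFR ligands and receptors (r = -0.488, rho = -0.524), cholangiocyte (r = -0.468, rho = -0.538), fibroblast and matrix (r = -0.383, rho = -0.395), smooth muscle (r = -0.371, rho = -0.343) and goblet cell means (r = -0.288, rho = -0.433) fell as well. The largest adjusted p among these was 0.0285, for goblet cells and mature colonocytes. The mesothelium list shares HP and C3 with the acute phase list, and the mature colonocyte list holds SLC4A4. HP and SLC4A4 were higher in liver biopsies (by 4.54 and 1.46), and only genes of the hepatocyte list had been left out. The rises of these list means therefore need not reflect the cell types they are named for.

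Alveolar and airway (r = -0.253, rho = -0.345, adjusted p = 0.0559), neutrophil and monocyte (r = 0.215, rho = 0.272, adjusted p = 0.108) and interferon gamma means (r = 0.169, rho = 0.144, adjusted p = 0.208) did not pass by r. Neither did red blood cell (r = 0.111, rho = 0.240, adjusted p = 0.414) and skeletal muscle means (r = -0.083, rho = -0.007, adjusted p = 0.541). All 28 values of r kept their sign without the 2 biopsies farthest from the median. Within the middle numbers of the titles 22 lists passed, goblet cells (r = -0.239, adjusted p = 0.0743) no longer among them, nor without the arrays that stand apart (r = -0.196, adjusted p = 0.162). The alveolar list passed with quantile normalization (adjusted p = 0.0243) and with the mean of all probe sets (adjusted p = 0.0219).

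Abdominal biopsies had lower levels of most hepatocyte genes than liver, and single matrix genes and the mucin MUC2 were higher. FGG was lower than in liver by -8.06 ± 1.17 (SE, 6 against 61 biopsies, adjusted p = 7.97e-06), ALB by -7.60 ± 1.19 (adjusted p = 3.07e-05) and CRP by -7.35 ± 1.18 (adjusted p = 4.25e-05), each in 6 of 6 biopsies below the liver median. MMP13 rose by 3.25 ± 0.57 (adjusted p = 0.000235), to 7.99 ± 4.28 (SD, n = 6) against 4.74 ± 0.44 in liver, with 5 of 6 above the liver median. The SE of MMP13 comes from the shared spread and understates its spread in abdomen. The gap junction gene GJA1 rose by 2.43 ± 0.43 (adjusted p = 0.000235) in 6 of 6. In all, 359 genes passed, 156 higher and 203 lower in abdomen.

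Of 31 hepatocyte genes 29 fell, and 31 adjusted over the list alone, with CYP2E1 at -6.12 ± 1.39. Of 17 acute phase genes 14 fell, and 17 adjusted over the list alone (both lists, camera adjusted p = 3.74e-49 and 3.9e-26, but adjusted p = 0.0528 for both with an estimated correlation). Of the urea cycle list 8 of 14 fell, 13 adjusted over the list alone, with MAT1A at -5.94 ± 1.21, and of drug metabolism 10 of 17, 15 adjusted over the list alone (both adjusted p = 0.0558 with an estimated correlation). Liver macrophage genes fell in 2 of 11, 7 adjusted over the list alone, with FCN3 at -4.16 ± 0.90 (adjusted p = 0.225 with an estimated correlation). FABP1 fell by 4.13 ± 0.80. The interferon gamma list rose in 2 of 15, 3 adjusted over the list alone, with the tryptophan enzymes WARS1 at 1.29 ± 0.30 and IDO1 at 1.77 ± 0.53 (camera adjusted p = 0.000161, but adjusted p = 0.436 with an estimated correlation). Goblet cell genes rose in 1 of 8, MUC2 at 2.71 ± 0.78, and in 4 adjusted over the list alone (camera adjusted p = 0.00909, but adjusted p = 0.396 with an estimated correlation).

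The fibroblast list rose by camera (adjusted p = 0.0171, but adjusted p = 0.82 with an estimated correlation) with 0 of 20 genes past the limma threshold and 1 adjusted over the list alone. Outside that list, MFAP5 rose by 3.16 ± 0.71, the matrix gene EPYC by 3.02 ± 0.62 and LRRC15 by 2.78 ± 0.55. Mature colonocyte genes fell by camera with 0 of 15 past the threshold, also adjusted over the list alone (adjusted p = 0.00213, but adjusted p = 0.0558 with an estimated correlation). So did skeletal muscle genes with 0 of 14 (adjusted p = 0.0222, but adjusted p = 0.82 with an estimated correlation). The desmosome gene DSC3 rose by 2.81 ± 0.67, CLDN18 by 2.61 ± 0.61, and the adipocyte genes FABP4 and ADIPOQ by 2.54 ± 0.63 and 2.03 ± 0.49. EGFR fell by 0.90 ± 0.28 (adjusted p = 0.0494), in 6 of 6 below the liver median. EREG at -0.30 ± 0.90 (adjusted p = 0.893), TGFA at -0.26 ± 0.35 (adjusted p = 0.738) and DUSP6 at 0.08 ± 0.25 (adjusted p = 0.897) did not pass.

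The count fell to 165 without abdomen replicate 1, 209 without replicate 2 and 153 without replicate 4, and was 322 without the arrays that stand apart. It rose to 744 with the title number as a factor, with 354 of the 359 among them. With the hepatocyte covariate it was 551, but only 86 of the 359 were among them. The split turned to 217 higher and 139 lower with the largest pseudocount and 107 and 74 with the biopsy of uncertain site added, and to 172 and 161 without replicate 3 and 219 and 211 without replicate 5. EGFR passed in 1 of the 6 fits that left out a biopsy, IDO1 in 2 and MUC2 in 3, against 6 of 6 for MMP13, GJA1 and DSC3. EPYC, CLDN18, FABP4, ADIPOQ and WARS1 passed in 4 of 6. In these fits MMP13 ranged from 1.91 to 3.96, EPYC from 2.04 to 3.89, CLDN18 from 1.74 to 3.19, FABP4 from 1.78 to 3.02, ADIPOQ from 1.12 to 2.68 and WARS1 from 0.98 to 1.53. EGFR did not pass without the arrays that stand apart.

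Lung biopsies had higher levels of alveolar genes than liver, and of some genes made by neutrophils, macrophages and B cells. The surfactant genes SFTPC and SFTPB rose against liver by 3.58 ± 0.54 (SE, 3 against 61 biopsies, adjusted p = 1.29e-05) and 2.81 ± 0.39 (adjusted p = 4.14e-06), each in 3 of 3 above the liver median. Their SDs in lung were 4.11 and 2.58, against 0.61 and 0.47 in liver, so these SEs, from the shared spread, understate the spread in lung. Lactoferrin (LTF), a neutrophil granule protein, rose by 4.26 ± 0.82 (adjusted p = 0.00152). The macrophage products CHIT1 and CCL18 rose by 3.99 ± 0.98 (adjusted p = 0.0215) and 3.66 ± 0.83 (adjusted p = 0.0106). Of 123 genes past the threshold, 101 were higher and 22 lower in lung. The lean toward higher values depended in part on scaling. The median difference of all genes was 0.104, and 0.023 with quantile normalization, where 120 genes were higher and 70 lower. The lung biopsies also covered few of the title numbers treated as a possible batch.

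Alveolar and airway genes rose in 3 of 9, 4 adjusted over the list alone, with LAMP3 at 2.39 ± 0.65 (camera adjusted p = 3.54e-06, and adjusted p = 0.039 with an estimated correlation). Neutrophil and monocyte genes rose in 4 of 14, 8 adjusted over the list alone. They were S100A9 at 2.62 ± 0.62, FCGR3B at 2.59 ± 0.61, FPR1 at 2.09 ± 0.52 and the receptor CSF3R at 2.05 ± 0.48 (camera adjusted p = 2.05e-08, but adjusted p = 0.148 with an estimated correlation). B and plasma cell genes rose in 2 of 10, 7 adjusted over the list alone, POU2AF1 at 2.40 ± 0.63 and CD79A at 2.20 ± 0.59 (camera adjusted p = 5.44e-06, but adjusted p = 0.216 with an estimated correlation). The macrophage list rose by camera (adjusted p = 4.45e-05, but adjusted p = 0.385 with an estimated correlation) with 0 of 10 genes past the threshold and 5 adjusted over the list alone. Outside it, the myeloid genes TREM2, TREM1 and HK3 rose by 2.81 ± 0.76, 2.70 ± 0.62 and 2.91 ± 0.72.

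Immediate early genes rose in 1 of 13, FOS at 2.38 ± 0.61 (camera adjusted p = 0.0014, but adjusted p = 0.315 with an estimated correlation). Among adipocyte genes LPL and CFD rose by 2.69 ± 0.73 and 1.96 ± 0.53, with the list as a whole not past the threshold (camera adjusted p = 0.517). Camera also called the interferon gamma, T and NK cell, skeletal muscle and ribosomal lists higher, with 0 genes of each past the threshold (adjusted p = 0.00162, 0.00733, 0.00363 and 0.0207, but adjusted p = 0.619, 0.725, 0.725 and 0.841 with an estimated correlation). Hepatocyte genes fell in 2 of 31 and in 27 adjusted over the list alone, ALB at -6.34 ± 1.64 and ITIH3 at -6.59 ± 1.71, with CRP at -6.62 ± 1.63 in the acute phase list (1 of 17, and 11 adjusted over the list alone). Those lists gave adjusted p = 0.207 and 0.216 with an estimated correlation. The cadherin CDH2 fell by 3.63 ± 0.86, the lectin COLEC11 by 3.30 ± 0.77 and the tight junction gene CLDN1 by 2.15 ± 0.52. EGFR at -0.69 ± 0.39 (adjusted p = 0.405), EREG at -0.43 ± 1.24 (adjusted p = 0.915), TGFA at -0.57 ± 0.48 (adjusted p = 0.621) and DUSP6 at 0.26 ± 0.34 (adjusted p = 0.789) did not pass.

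Fewer genes passed whenever a lung biopsy was left out, which leaves 2 in the group. SFTPC, SFTPB and LTF passed in 2 of the 3 fits that left out a biopsy, and the other genes named here in 1 or 0. By count, 17 genes passed without lung replicate 1, 36 without replicate 2 and 21 without replicate 3, and SFTPC did not pass without replicate 3. In these fits SFTPC ranged from 1.27 to 5.21, SFTPB from 1.38 to 3.90, LAMP3 from 1.14 to 3.03 and POU2AF1 from 1.45 to 3.49. TREM2 moved little, from 2.66 to 3.02, as did LPL, from 2.51 to 2.81, and COLEC11, from -3.42 to -3.22, although they passed in 0 of the 3. A lost threshold alone therefore does not show that a gene depended on 1 biopsy. The count was 29 with the title number as a factor, 78 with the stricter filter, 119 without the arrays that stand apart, 190 with quantile normalization (120 higher and 70 lower), 271 with the largest pseudocount, 353 with the hepatocyte covariate (91 of the 123 among them) and 422 with array weights.

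**Figure D2:**
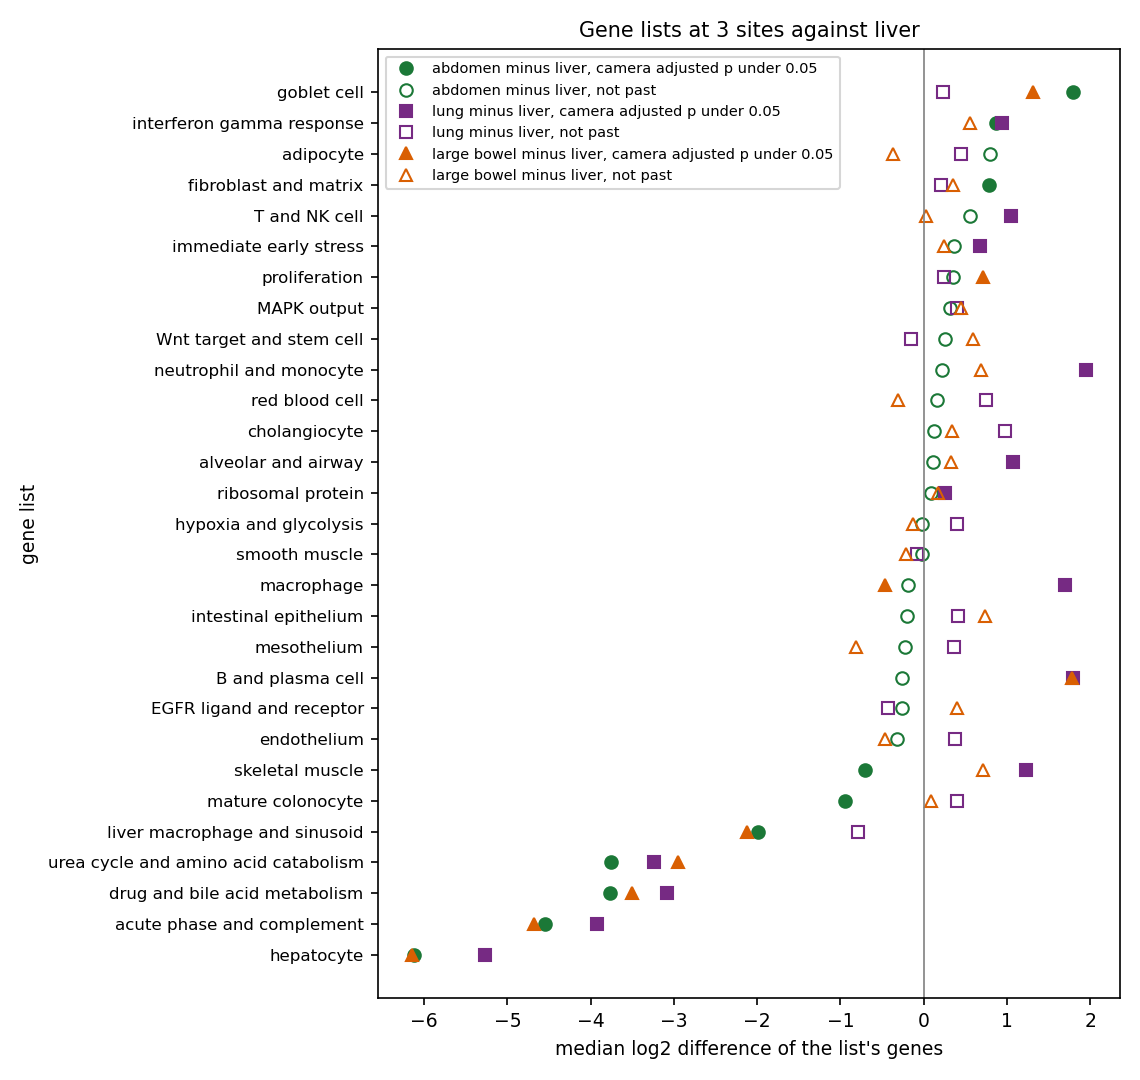
Median log2 difference of the genes of each of 29 lists (vertical axis) for abdomen, lung and large bowel against liver (horizontal axis); filled symbols mark lists past camera's threshold at the preset correlation. Hepatocyte genes lie lowest at all 3 sites, and neutrophil, macrophage and alveolar lists are called higher in lung, of which only the alveolar list passes with an estimated correlation (adjusted p = 0.148, 0.385 and 0.039).

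Biopsies of the large bowel differed from liver in 16 genes, 4 higher and 12 lower. The stromelysin MMP3 rose by 4.70 ± 0.79 (SE, 3 against 61 biopsies, adjusted p = 0.000428), to 11.41 ± 1.04 (SD, n = 3) against 6.71 ± 1.32, and MMP13 by 3.54 ± 0.79 (adjusted p = 0.0224), each in 3 of 3 above the liver median. The other rises were PABPN1 at 1.58 ± 0.27 (adjusted p = 0.000428) and BCL2L2 at 1.27 ± 0.25 (adjusted p = 0.00349). The SDs of PABPN1 and BCL2L2 were 1.67 and 1.66 in large bowel, against 0.37 and 0.32 in liver. Their SEs, from the shared spread, understate the spread in large bowel. Among the falls were ORM1 at -9.11 ± 1.82, FGG at -8.60 ± 1.62, ALB at -8.47 ± 1.64, APOH at -8.22 ± 1.88, and CRP at -7.40 ± 1.63. Others were HP at -7.22 ± 1.63, IGFBP1 at -5.93 ± 1.29, COLEC11 at -4.49 ± 0.77 and CDH2 at -3.75 ± 0.86, with adjusted p from 0.000428 to 0.0271.

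Hepatocyte genes fell in 5 of 31 and acute phase genes in 3 of 17, and in 31 and 16 adjusted over the list alone (camera adjusted p = 6.2e-41 and 1.3e-23, but adjusted p = 0.0818 for both with an estimated correlation). The drug metabolism, urea cycle and liver macrophage lists fell by camera with 0 genes past the threshold (adjusted p = 2.28e-12, 4.88e-09 and 1.32e-05, but adjusted p = 0.308, 0.405 and 0.405 with an estimated correlation), as did the macrophage list (adjusted p = 0.0287, but adjusted p = 0.792 with an estimated correlation). B and plasma cell genes rose by camera (adjusted p = 0.000348, but adjusted p = 0.405 with an estimated correlation) with 0 of 10 past the threshold and 3 adjusted over the list alone; POU2AF1 stood at 2.23 ± 0.63 (adjusted p = 0.123). Goblet cell genes (adjusted p = 0.0457, but adjusted p = 0.633 with an estimated correlation) and proliferation genes (adjusted p = 0.0287, but adjusted p = 0.792 with an estimated correlation) rose by camera too, with MUC2 at 3.04 ± 1.08 (adjusted p = 0.236). EREG at 0.54 ± 1.24 (adjusted p = 0.867), EGFR at 0.20 ± 0.39 (adjusted p = 0.84), TGFA at 0.13 ± 0.48 (adjusted p = 0.921) and DUSP6 at 0.02 ± 0.34 (adjusted p = 0.987) did not pass.

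Without large bowel replicate 3 the count fell to 2, and PABPN1, at 0.66, and BCL2L2, at 0.31, did not pass, whereas MMP3 passed in all 3 fits that left out a biopsy. ORM1, APOH, CRP, HP and CDH2 passed in 0 of these 3 fits, ALB, IGFBP1 and MMP13 in 1, and FGG and COLEC11 in 2. The differences of ORM1 (-9.23 to -9.01) and HP (-7.33 to -7.11) moved little, so their lost thresholds do not show that they depended on 1 biopsy. The count was 26 with a pseudocount of 1, 7 with 64 and 5 with the largest. It was 31 with array weights, 8 with the title number as a factor, 42 with the RNA quality covariate, 3 with the biopsy of uncertain site added and 15 without the arrays that stand apart. The split turned to 10 higher and 7 lower with the hepatocyte covariate, 10 and 8 without replicate 1, 4 and 1 with the largest pseudocount, 2 and 1 with the uncertain biopsy added and 2 and 0 without replicate 3.

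Between lung and abdomen 10 genes passed, 5 in each direction. SFTPC rose in lung by 3.84 ± 0.64 (SE, 3 against 6 biopsies, adjusted p = 0.000674) and SFTPB by 2.70 ± 0.47 (adjusted p = 0.000751), each in 3 of 3 above the abdomen median. The limit of the shared spread given above for these genes in lung applies here too. WIPF2 at 1.97 ± 0.38 (adjusted p = 0.00681), RARA at 1.64 ± 0.38 (adjusted p = 0.037) and PSMD3 at 1.59 ± 0.36 (adjusted p = 0.0306) also rose. RITA1 fell by 1.74 ± 0.35, C17orf75 by 1.59 ± 0.34, PTPRG by 1.52 ± 0.34, BBS10 by 1.42 ± 0.31 and the proteasome subunit PSMA4 by 0.94 ± 0.21, with adjusted p from 0.0078 to 0.0306.

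Camera called neutrophil (adjusted p = 3e-09), B and plasma cell (adjusted p = 2.26e-08), macrophage (adjusted p = 2.26e-08), skeletal muscle (adjusted p = 1.71e-07) and alveolar lists (adjusted p = 6.82e-05) higher in lung. With an estimated correlation these gave adjusted p = 0.0743, 0.124, 0.201, 0.268 and 0.0743. Apart from SFTPB and SFTPC, 0 of their genes passed, and 4 of 14 neutrophil, 5 of 10 B and plasma cell, 4 of 10 macrophage and 0 of 14 skeletal muscle genes did when adjusted over the list alone. MARCO stood at 4.32 ± 1.31 (adjusted p = 0.27), IGKC at 3.47 ± 1.20 (adjusted p = 0.402) and CSF3R at 2.21 ± 0.58 (adjusted p = 0.126). The liver macrophage, mature colonocyte, hypoxia and intestinal epithelium lists were also higher (adjusted p = 0.00794, 0.00794, 0.00889 and 0.0425, but adjusted p = 0.759, 0.124, 0.549 and 0.895 with an estimated correlation). Goblet cell genes were lower (adjusted p = 0.00337, but adjusted p = 0.268 with an estimated correlation). EREG (-0.13 ± 1.48), EGFR (0.20 ± 0.46), TGFA (-0.31 ± 0.57) and DUSP6 (0.18 ± 0.41) had an adjusted p of 0.996.

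The count was 22 without lung replicate 2, 2 without lung replicate 3, 5 without abdomen replicate 1 and 25 without abdomen replicate 4, and SFTPB, SFTPC and WIPF2 were among the genes that did not pass without lung replicate 3. With 1 biopsy left out SFTPC ranged from 1.53 to 5.47, SFTPB from 1.28 to 3.79, WIPF2 from 1.12 to 2.79, RARA from 0.97 to 2.41, PSMD3 from 0.80 to 2.62 and RITA1 from -2.16 to -1.06. It was 22 without a filter or with the hepatocyte covariate, 20 with the largest pseudocount, 17 with array weights, 6 with the title number as a factor and 10 without the arrays that stand apart; quantile normalization gave 5 higher and 8 lower.

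Between large bowel and abdomen limma called 0 genes, with 496 at an unadjusted p under 0.05. B and plasma cell genes rose in large bowel by camera (adjusted p = 1.01e-05, but adjusted p = 0.988 with an estimated correlation and 0.776 by fry) with 5 of 10 genes past the threshold adjusted over the list alone. The immunoglobulin genes IGKC, IGLL5 and JCHAIN stood at 3.60 ± 1.20 (SE, 3 against 6 biopsies, adjusted p = 0.673), 2.71 ± 1.00 (adjusted p = 0.734) and 3.54 ± 1.44 (adjusted p = 0.778). Camera also called skeletal muscle and intestinal epithelium genes higher (adjusted p = 0.00363 and 0.00379, but adjusted p = 0.988 for both with an estimated correlation and 0.962 by fry). CDX1 stood at 1.54 ± 1.02 (adjusted p = 0.981). EGFR stood at 1.09 ± 0.46 (adjusted p = 0.798), and EREG, TGFA and DUSP6 at 0.84 ± 1.48, 0.39 ± 0.57 and -0.06 ± 0.41. The count was 9 without large bowel replicate 1, 5 without replicate 2 and 6 without abdomen replicate 5, and at most 2 in every other alternative.

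Among the 61 liver biopsies EREG ran from 4.25 to 12.86 on the log2 scale, and 2513 of 8975 genes varied with it in a fit that held the hepatocyte mean as a covariate, 1899 rising and 614 falling. The chloride transporter SLC26A3 rose by 2.0 ± 0.36 on the log2 scale for each SD of EREG (SE, adjusted p = 3.72e-05), the adhesion gene CEACAM5 by 1.54 ± 0.27 (adjusted p = 2.08e-05). KRT23 rose by 1.46 ± 0.24 (adjusted p = 1.29e-05) and the epithelial gene EPCAM by 1.24 ± 0.20 (adjusted p = 5.67e-06). The transcription factors MYB and MYC rose by 1.31 ± 0.19 (adjusted p = 1.4e-06) and 0.70 ± 0.10 (adjusted p = 1.34e-06). CXCL13 fell by 0.87 ± 0.19 (adjusted p = 0.000564) and DUSP6 by 0.31 ± 0.08 (adjusted p = 0.00234).

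The number of genes past the threshold depended on 4 liver arrays and on a covariate for tumour epithelium. The 4 arrays stood apart in their correlation with the others, and had hepatocyte means of 1.22 to 1.39, intestinal epithelium means of -2.67 to -2.19, against -1.18 to 0.83 in the other 57, and EREG of 4.25 to 5.77. Without them 269 genes passed, 230 rising and 39 falling, of which 257 were among the 2513. With the mean of the intestinal epithelium list as a further covariate 44 passed. Of the 40 genes named here that passed, 16 did so without the 4 arrays: SLC26A3, KRT23, EPCAM, CDX1, CDX2, MYB, MYC, RNF43, UBE2C, TPX2, CFTR, DUSP6, EGR1, CXCL13, NT5E and C4BPB. Among the others CD163 (-0.49), C1QA (-0.52), ETV1 (-0.64) and PLA2G2A (-0.90) did not pass although their slopes did not shrink, so a lost threshold alone does not show that a gene depended on these arrays. Other slopes did shrink without the 4 arrays, such as those of CEACAM5 (0.41) and KRT19 (0.19). Among the genes that still passed, EPCAM (0.28) and MYB (0.60) also had much smaller slopes than in the main fit. With the epithelium covariate 3 passed, SLC26A3, CXCL13 and NT5E. DUSP6 (-0.33) and EGR1 (-0.42) did not pass with it although their slopes did not shrink, while those of CEACAM5 (0.18) and EPCAM (0.28) did.

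Genes of intestinal epithelium rose with EREG in 16 of 20, 19 adjusted over the list alone (camera adjusted p = 4.59e-09, but adjusted p = 0.253 with an estimated correlation). CDH17 rose by 1.31 ± 0.24, KRT19 by 1.39 ± 0.27, GPA33 by 1.27 ± 0.22, KRT20 by 1.00 ± 0.29 and the intestinal transcription factors CDX2 and CDX1 by 1.00 ± 0.17 and 0.95 ± 0.15. Without the 4 arrays CDH17 (0.36), KRT19 (0.19), GPA33 (0.73) and KRT20 (0.17) did not pass, whereas CDX2 (0.69) and CDX1 (0.60) did. Proliferation genes rose in 24 of 25, also adjusted over the list alone, with UBE2C at 0.91 ± 0.14, TOP2A at 0.86 ± 0.15, TPX2 at 0.73 ± 0.12 and CCNA2 at 0.71 ± 0.12 (camera adjusted p = 3.58e-13, but adjusted p = 0.253 with an estimated correlation). Wnt target and stem cell genes rose in 8 of 11, 9 adjusted over the list alone, with SOX9 at 0.79 ± 0.13, the ubiquitin ligase RNF43 at 0.76 ± 0.11, ASCL2 at 0.70 ± 0.16 and OLFM4 at 1.36 ± 0.49 (camera adjusted p = 0.000255, but adjusted p = 0.253 with an estimated correlation). Cholangiocyte genes rose in 4 of 8, also adjusted over the list alone, with CFTR at 1.21 ± 0.19 (camera adjusted p = 0.0168, but adjusted p = 0.371 with an estimated correlation). Also past the threshold were PLCB4 at 1.46 ± 0.26, the matrix genes POSTN at 0.75 ± 0.20 and COL1A1 at 0.56 ± 0.20, and TFF3 at 0.71 ± 0.24. None of these 4 passed without the 4 arrays (0.68, 0.25, 0.047 and 0.019) or with the epithelium covariate, where TFF3 turned to -0.28 and KRT20 to -0.30.

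Most genes of the macrophage lists fell with EREG in the main fit. In the liver macrophage and sinusoid list 8 of 11 fell, 10 adjusted over the list alone, with MARCO at -0.75 ± 0.20, FCN3 at -0.49 ± 0.13 and the scavenger receptor CD163 at -0.47 ± 0.12. In the macrophage list 7 of 10 fell, 9 adjusted over the list alone, with C1QA at -0.49 ± 0.15 and CD14 at -0.45 ± 0.12. Camera gave adjusted p = 4.18e-07 and 2.34e-06, but adjusted p = 0.253 for both with an estimated correlation. None of the macrophage genes named here passed without the 4 arrays, where their slopes ran from -0.68 (MARCO) to -0.39 (CD14). With the epithelium covariate none passed either, and all their slopes shrank, to between -0.28 (MARCO) and -0.13 (CD14). The urea cycle, drug metabolism and acute phase lists fell in 4 of 14, 4 of 17 and 5 of 17, and in 5, 4 and 5 adjusted over the list alone, with C4BPB at -0.58 ± 0.12. Camera gave adjusted p = 0.000308, 0.000181 and 0.000819, but adjusted p = 0.371, 0.253 and 0.253 with an estimated correlation. Neutrophil, interferon gamma, T and NK cell, and B and plasma cell lists also fell by camera (adjusted p = 0.00541, 0.00315, 0.0168 and 0.0195, but adjusted p = 0.518, 0.518, 0.673 and 0.547 with an estimated correlation), with 2, 1, 1 and 0 genes falling past the threshold.

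The MAPK output list split, with 4 of 22 genes rising and 4 falling, and 6 and 4 adjusted over the list alone (camera adjusted p = 0.969). ETV4 and MYC rose, ETV4 by 0.71 ± 0.14, while DUSP6, ETV1 at -0.61 ± 0.17 and EGR1 at -0.36 ± 0.10 fell. Of the EGFR family, the ligand HBEGF rose by 0.38 ± 0.13 (adjusted p = 0.0249), but turned to -0.042 (adjusted p = 0.888) without the 4 arrays and to -0.16 with the epithelium covariate. ERBB2 stood at 0.30 ± 0.12 (adjusted p = 0.0505) and EGFR at -0.13 ± 0.09 (adjusted p = 0.303). The ectonucleotidase NT5E fell by 0.67 ± 0.15, PLA2G2A by 0.77 ± 0.27 and CA2 by 0.53 ± 0.14, and FCGBP stood at -0.57 ± 0.23 (adjusted p = 0.0537). Without the hepatocyte covariate 5236 genes passed, with array weights 3943 and with the largest pseudocount 1419, and quantile normalization gave 1544 rising and 988 falling.

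Of 7 correlations of EREG with fixed partners in liver (n = 61), 6 passed. EREG rose with CDX2 (r = 0.695, rho = 0.533) and SLC26A3 (r = 0.634, rho = 0.637), each at a permutation p of 1e-05, the smallest possible, and an adjusted p of 3.5e-05. Without the 2 farthest biopsies r was 0.624 and 0.638, and within the title numbers 0.664 and 0.611. EREG fell with the hepatocyte mean (r = -0.451, p = 0.00019, adjusted p = 0.000443; rho = -0.467, adjusted p = 0.00042; r = -0.400 without 2 biopsies; r = -0.382 within title numbers). It fell with DUSP6 as well (r = -0.328, p = 0.00943, adjusted p = 0.0119; rho = -0.407, adjusted p = 0.00217; r = -0.339 without 2 biopsies; r = -0.397 within title numbers). These p-values come from permutation.

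The correlations with TGFA (r = 0.328, permutation p = 0.00957, adjusted p = 0.0119; 0.269 within title numbers) and EGFR (r = -0.328, permutation p = 0.0102, adjusted p = 0.0119; -0.306 within title numbers) passed by r. They did not by rho (0.251 with adjusted p = 0.0696, and -0.184 with adjusted p = 0.181). Without the 2 farthest biopsies r was 0.247 (permutation p = 0.0604) and -0.255 (permutation p = 0.051). Without the arrays that stand apart r was 0.108 and -0.125 (permutation, adjusted p = 0.426 for both). PHLDA1, a MAPK target, did not pass (r = 0.225, rho = -0.022, permutation p = 0.0801 and 0.866, adjusted p = 0.0801 and 0.866, r = 0.102 without 2 biopsies, 0.178 within title numbers). In the 19 biopsies outside the liver CDX2 again rose with EREG (r = 0.635, permutation, adjusted p = 0.0234), but not past the threshold without the 2 farthest biopsies (r = 0.437, permutation p = 0.0805). There r was 0.519 for SLC26A3, -0.026 for DUSP6, 0.153 for TGFA, 0.129 for PHLDA1, -0.302 for the hepatocyte mean and, with the other sign, 0.442 for EGFR (adjusted p = 0.134 by permutation, and 0.0714 by rho), none of them past the threshold. Without the 2 farthest of these biopsies r was 0.680 for EGFR (permutation p = 0.00267, unadjusted), 0.502 for SLC26A3 (p = 0.0417) and -0.153 for DUSP6. It turned for TGFA (-0.127), PHLDA1 (-0.278) and the hepatocyte mean (0.237).

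**Figure D3:**
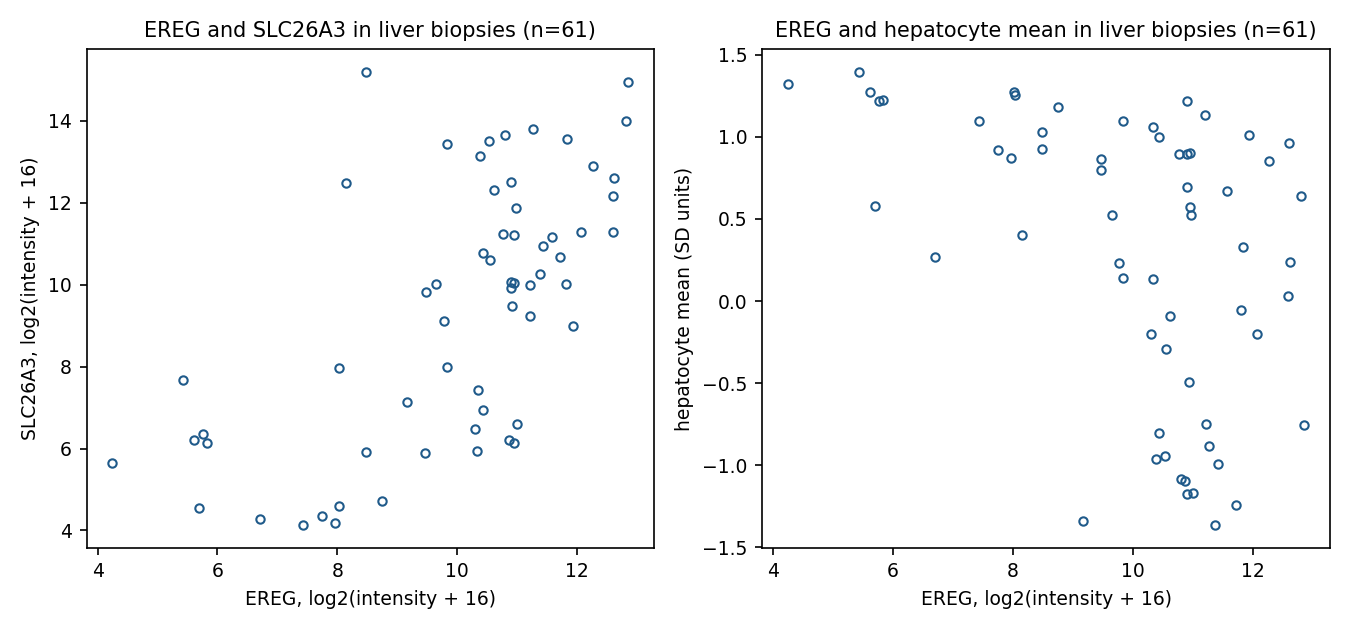
log2(intensity + 16) of EREG (horizontal axis) in 61 liver biopsies against that of SLC26A3 (left) and against the hepatocyte mean in SD units (right); each circle is a biopsy. SLC26A3 rises with EREG (r = 0.634) and the hepatocyte mean falls (r = -0.451).

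In the 19 biopsies outside the liver 24 genes varied with EREG in a fit without the hepatocyte covariate, 20 rising and 4 falling. At an unadjusted p under 0.05 there were 1558. The biopsy of uncertain site was among the 19, with the lowest EREG (4.47), a hepatocyte mean of 1.16 and an intestinal epithelium mean of -2.24. The share of tumour in the biopsy was not separated in this fit. All 24 genes had a slope of the same sign in liver, where the fit held the hepatocyte covariate, and the 20 that rose also rose past the threshold there. Of these 20, 8 lie on chromosome 20, which holds 255 of 8974 tested genes: CPNE1, DDX27, EIF2S2, ERGIC3, KIF16B, PLAGL2, PPP1R3D and PRPF6. They were singled out after their values were seen. The transcription factor PLAGL2 had slopes of 0.75 ± 0.09 outside the liver (SE, n = 19) and 0.71 ± 0.10 in liver (n = 61). EREG itself lies on chromosome 4.

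In liver the mean t of the genes of chromosome 20 exceeded that of all other genes by 1.497, and outside the liver, without the hepatocyte covariate, by 1.49. The genes of chromosomes 13 and 7 stood higher in liver as well, by 0.89 and 0.50, and those of chromosomes 18 and 14 lower, by -0.97 and -0.62. With the epithelium covariate these values were 0.48, 0.33, -0.39 and -0.36. Of the 2513 genes that varied with EREG in liver, 2315 (92.1%) had a slope of the same sign outside it, against 74.7% of all genes. A test of the difference between the 2 slopes called 0 of 8975 genes with limma, and 967 at an unadjusted p under 0.05. Those 967 are more than the 1 in 20 that chance gives on average. The smallest adjusted p was 0.0774 (limma). Genes at that value included POSTN and COL11A1, with slopes higher in liver by 1.497 and 1.982, and PDK2, with the opposite difference (-0.529). The lack of calls therefore does not show that the slopes were alike.

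**Figure D4:**
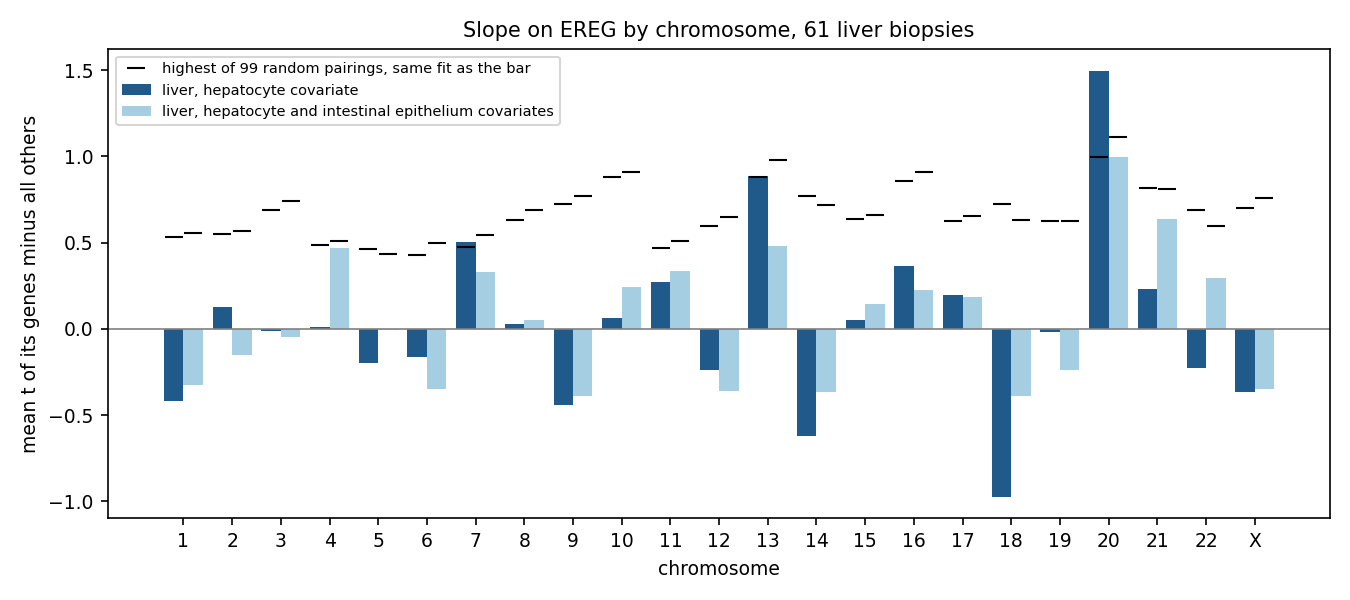
Mean t for EREG of the genes of each chromosome (horizontal axis) minus that of all other genes (vertical axis) in 61 liver biopsies. Dark bars are from the fit with the hepatocyte covariate, and light bars from that with the intestinal epithelium mean as well. Dashes mark the highest of 99 random pairings of EREG with biopsies. Chromosome 20 stands highest in both fits, at 1.497 and 0.998.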

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

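The values here are those that set 1 biopsy apart from the others of its group by Dixon's test at the 95% level. Groups of 6 and 7 biopsies were tested, those of 3 and of more than 10 were not. Of 74 tests, on 37 measures in abdomen and other sites, 14 set a biopsy apart, 3 in abdomen and 11 in other sites, where chance gives about 1 in 20, or 3.7. The biopsies of other sites come from different organs. The splits of the biopsies were planned before the data were examined.

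In abdomen, replicate 4 had the lowest TGFA level, at 8.5725 on the log2 scale against 9.73 for the nearest, and the lowest mean of the intestinal epithelium list, at -2.004 against -0.12. Replicate 3 had the highest mean of the red blood cell list, at 1.7004 against -0.026.

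Among the other sites, replicate 6 was apart in 6 measures. It had the lowest TGFA level, at 7.8875, the lowest means of the intestinal epithelium list (-2.2387), the proliferation list (-2.1546), the EGFR ligand and receptor list (-1.3306) and the cholangiocyte list (-0.5889), and the highest mean of the liver macrophage and sinusoid list (1.4906). Replicate 1 had the highest mean of the skeletal muscle list, at 4.3853 against 0.376. Replicate 3 had the lowest fibroblast and matrix mean (-1.7664), the highest ribosomal protein mean (2.4078), the highest array median (587.8 intensity units against 481.4) and the highest share of signal in its 50 brightest probe sets (17.4136% against 8.16%). No explanation of these values was tested.

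Other splits of the same biopsies into groups of the same sizes were refitted. For liver against all other sites the splits argue against chance: 1 of 100 splits, the real one, reached its 1053 genes, and the highest of the others called 760. For lung against liver they argue against chance as well (1 of 100 splits, 123 genes, highest other 24). With 100 splits the share cannot fall below 1 in 100, and it was not adjusted over the comparisons, so chance is not excluded. For large bowel against liver 3 of 100 splits called at least the 16 genes of the real one, with a highest other of 30, which is under 5%. For abdomen against liver 3 of 100 splits called at least 359 genes, also under 5%, but the highest other called 2664, several times the real count. The reason for that high count was not tested. The median over the other splits was 0. For lung against abdomen chance cannot be excluded: 16 of 84 splits called at least 10 genes and the highest other 384. For large bowel against abdomen the real split called 0 genes, which all 84 of 84 splits reach by construction, so this says nothing about chance. The highest other split called 738, with a median of 1. What drove that split was not tested.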

How the results depend on the processing

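Chosen after the data had been seen were the largest pseudocount, the fits without the arrays that stand apart, the fit without the 7 biopsies of other sites, the epithelium covariate, the correlations within title numbers, and list correlations outside the liver. All other alternatives were fixed beforehand. Of 3404 values that alternatives gave for 186 named gene results, 3036 kept direction and side of the threshold, 341 lost the threshold, 12 gained it and 15 turned. Of 231 values for counts and correlations, 158 were the same, 60 counts moved by more than 1.5 times, 11 correlations lost the threshold, 1 gained it and 1 turned. Of 168 values for list means against the hepatocyte mean, 164 were the same, 2 lost the threshold (goblet cells) and 2 gained it (alveolar). These leave out the 19 biopsies outside the liver, where 4 of 28 lists passed, all 4 upward, 1 by rho, and 15 of 28 kept their sign without the 2 farthest biopsies. Unless stated, the cause was not tested.

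Liver against all other sites (1053 genes) moved to 695 with the stricter filter, which tests fewer genes. With the hepatocyte covariate 889 passed, but only 216 of the 1053 were among them. Abdomen against liver (359) moved to 744 with the title number as a factor, 551 with the hepatocyte covariate (86 of the 359 among them) and 181 with the uncertain biopsy added, and ranged from 153 to 430 when a biopsy was left out. Lung against liver (123) moved to 271 with the largest pseudocount, 190 with quantile normalization, 78 with the stricter filter, 422 with array weights, 29 with the title number and 353 with the hepatocyte covariate, and ranged from 17 to 36 when a biopsy was left out. Large bowel against liver (16) moved to 26, 7 and 5 with pseudocounts of 1, 64 and the largest, and 31 with array weights. It was 8 with the title number, 42 with the RNA quality covariate and 3 with the uncertain biopsy added, and ranged from 2 to 18 when a biopsy was left out. The uncertain biopsy had a hepatocyte mean of 1.16, inside the range of liver, against at most -1.03 in abdomen and -1.22 in large bowel.

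Lung against abdomen (10) moved to 20 with the largest pseudocount, 22 without a filter, 17 with array weights, 6 with the title number and 22 with the hepatocyte covariate, and ranged from 2 to 25 when a biopsy was left out. Large bowel against abdomen (0 with limma, 496 at an unadjusted p under 0.05) moved to 1 with a pseudocount of 64, 2 with the largest, 1 with quantile normalization and 1 with the stricter filter. It was 1 with the title number, 2 with the hepatocyte covariate, 1 with other sites kept as a group of their own and 1 with the uncertain biopsy added to abdomen, and ranged from 0 to 9 when a biopsy was left out. Genes that vary with EREG in liver (2513) moved to 1419 with the largest pseudocount, 3943 with array weights, 5236 without the hepatocyte covariate, 44 with the epithelium covariate and 269 without the arrays that stand apart.

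The lists called by camera (11, 10, 13, 9, 10, 3 and 13 in the order above) moved to 4, 0, 1, 0, 0, 0 and 0 with an estimated correlation, which takes the correlation within each list from the data. With fry they moved to 5 for lung against liver, 2 for large bowel against liver, 2 for lung against abdomen and 0 for large bowel against abdomen.

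The correlation of EREG with PHLDA1 passed with a pseudocount of 1 (0.258, permutation p = 0.0448). That with TGFA did not pass with quantile normalization (0.260), the mean of all probe sets (0.190), as a partial correlation given the hepatocyte mean (0.135), outside the liver (0.153) or without the arrays that stand apart (0.108). That with EGFR did not pass as a partial correlation (-0.175), in all 80 biopsies (-0.110) or without those arrays (-0.125). Outside the liver EGFR turned (0.442), and DUSP6 (-0.026), SLC26A3 (0.519) and the hepatocyte mean (-0.302) did not pass, with fewer biopsies.

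With the hepatocyte covariate, which is built from liver-cell genes that include CYP2E1, CYP2C8 and HPD, 10 genes turned in liver against all other sites and none passed: BAAT (-0.13), FCN3 (-0.019), SLC4A4 (-0.29), CYP2E1 (-0.093), CYP2C8 (-0.53), ARG1 (-0.57), HPD (-0.035), CRHBP (-0.82), CLEC1B (-0.29) and PLAUR (0.16). CYP2E1 turned in abdomen against liver (0.022). With the epithelium covariate HBEGF (-0.16), TFF3 (-0.28) and KRT20 (-0.30) turned in the EREG fit, and HBEGF turned without the arrays that stand apart (-0.042).

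Alternatives that used a second EGFR ligand were not run. No paired analysis was possible because each patient gave 1 biopsy. A pseudocount of 16 shrinks the differences of dim genes.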

Other observations

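Of the tests in this part, 2 were chosen after the result was seen: the slopes of the EREG calls lost with the epithelium covariate, and the reading of dilution from tumour epithelial genes. The epithelium covariate itself, used for the EREG calls and for chromosome 20, was also added after the data had been seen. The bounds for those tests were written before they were run. The chromosome 20 pattern was noticed outside the liver and then tested in the liver biopsies.

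For the 2513 genes that varied with EREG in liver a chance pairing of EREG with arrays is argued against. Only 1 of 100 pairings, the real one, gave as many, and the highest other gave 2. RNA quality as the whole cause is argued against, as 2600 genes passed with its covariate. With the mean of the intestinal epithelium list as a covariate 2481 of the 2513 calls were lost, and the median ratio of their slopes with and without it was 0.437 (quartiles 0.246 and 0.642), so the share of tumour epithelium in the biopsy may account for a part. It cannot be told apart from other causes for the lost calls as a set, since slopes shrank to under 0.5 of their size in 1450, not in 1031, and not at all in 113, while standard errors grew by a median factor of 1.17. The list holds genes that rise with EREG themselves, so the covariate can also remove change within tumour cells. With this covariate 44 genes passed, 32 of them among the 2513, against a highest other of 2. The bound set before that test counts this against tumour share as the whole cause. Random pairings also break any link of EREG with tumour share, so they address chance only. Tumour share that the list mean does not capture therefore stays open, and no biological explanation was tested.

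The rise of chromosome 20 genes with EREG, noticed outside the liver, recurred in liver at 1.497, above the highest of 99 random pairings (0.994). Chromosomes 13 (0.886 against 0.880) and 7 (0.503 against 0.475) also lay above all pairings in that fit, though narrowly. Chromosomes 18 and 14 had 100 of 100 pairings as high, so chromosome 20 was not the only one shifted. With the epithelium covariate the value for chromosome 20 was 0.998, and 1 of 99 pairings was higher, at 1.111. By the bound set beforehand, tumour share is therefore not excluded. Lying inside the range of the pairings was also the outcome set beforehand as counting against extra copies of chromosome 20 in tumours with high EREG. That outcome was met narrowly. Chromosome 20 ranked 1 of 23 chromosomes in that fit, but chromosomes 21 (0.634) and 4 (0.470), the latter holding EREG, also had 2 of 100 pairings as high, the real one included, so chromosome 20 was not singular there. Chromosomes 13 (0.48) and 7 (0.33) had 14 and 15 of 100. Extra copies were not tested directly, since the arrays measured RNA and no copy number was analysed here.

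The 15 genes with the largest fall in liver, among them MMP13, MFAP5, COL11A1, LRRC15 and PRRX1, had a median of -2.047. With the hepatocyte covariate the median was -1.867, with 13 of 15 past the threshold and a median SE of 0.445. By the bound set beforehand this counts against dilution of tumour RNA by liver cells as the whole cause. The covariate can miss dilution, however. The 4 liver arrays that stand apart had hepatocyte means of 1.22 to 1.39, against up to 1.27 in the others, but far lower intestinal epithelium means (-2.67 to -2.19 against at least -1.18). Dilution is therefore not excluded. The tumour epithelial genes had a median of -0.234 over 17 genes with an interquartile range of 0.429, a small fall for those genes as a set. The 15 genes were picked as the largest falls, so their more extreme median was fixed by that choice and does not decide the question. With the RNA quality covariate 15 of 15 passed. A difference between the tissue of the sites stays open and was not tested, and other sites mix several organs.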
